A study of Mus musculus with 18 samples.

How the data were processed

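RNA-seq was measured in 18 libraries of mouse cells, which the labels place in 9 groups of 2 libraries. Per the labels' protocols, mouse embryonic stem cells (mESCs) were grown on gelatin with leukemia inhibitory factor (LIF), and the FLAG-EED knock-in mESCs also with inhibitors of MEK and GSK3, together called 2i. Embryoid bodies were grown in suspension on a rotary shaker without LIF and 2i. Total RNA was isolated with an RNeasy kit and made into libraries with a VAHTS Total RNA-seq kit, per the labels' protocols. The knock-in cells carry FLAG-tagged EED of wildtype sequence (FLAG-WT) or with the K19R substitution (K19R). How many clones were used, and how the wildtype mESCs relate to the knock-in cells, is not given in the sources used here.

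The deposited values were raw counts of read pairs per gene name, not normalized and not pooled over replicates, per the file headers. The counts were made by the authors with featureCounts 1.6.3 for the 16 FLAG-EED libraries and 1.6.4 for the wildtype mESCs, over exons of the GENCODE vM19 annotation of GRCm38, per the file headers. The recorded command kept pairs with both ends mapped and left out chimeric pairs, and it gave no strand option. Reads from overlapping or antisense genes, such as Xist and Tsix, were therefore uncertain. Counts of near-identical genes (the Zscan4 and Usp17l families and X- and Y-linked copies such as Uba1y) were uncertain too, since reads that map to several places were left out at the default setting. The submitters' processing notes name bcl2fastq 2.17, FastQC 0.11.7, Trim Galore 0.6.0 and STAR 2.7.0c, with no settings given in the sources used here. Positions are those of the deposited annotation columns, on GRCm38, counted from 1.

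The FLAG-EED table held 54429 gene names and that of the wildtype mESCs 54352. The 77 names found only in the former all lay on unplaced scaffolds, and 6 shared names had another exon length. The comparison of wildtype mESCs with FLAG-WT cells used the 54352 shared names. Total counts ran from 20158077 to 28917558 in the 16 FLAG-EED libraries and were 14190166 and 37375083 in the wildtype mESCs. Replicates of each of the 9 groups differed by more than sampling noise, with a chi-square of 2.28 to 11.2 per degree of freedom and Pearson correlations of log2 CPM across genes of 0.990 to 0.994. No pair was therefore taken for a repeat of 1 library. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

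The groups, gene lists, tests, alternatives and rule for named genes were fixed before the data were examined. Genes were kept with filterByExpr (a count minimum of 10 per library and 15 in total, by group), which left 19092 genes. Counts were scaled by trimmed mean of M-values (TMM) and fitted with edgeR 4.0.16 (glmQLFit, 1 coefficient per group) in R 4.3.3. The 16 FLAG-EED libraries entered a single fit with 8 residual degrees of freedom, and the wildtype mESCs were compared in a fit of all 18 libraries with 9 residual degrees of freedom and 19296 genes. Each of 14 comparisons was tested with edgeR's two-sided quasi-likelihood test (glmQLFTest), and p was adjusted over genes by Benjamini-Hochberg with a threshold of 0.05. They were K19R against FLAG-WT at each of 4 days, each later day against day 0 in each line, the change of the genotype difference from day 0 to each later day, and wildtype mESCs against FLAG-WT at day 0. Levels are CPM (counts scaled to a common library size) with TMM factors, given as mean ± SD over 2 libraries. Changes are log2 fold changes ± SE, the SE being the absolute change over the square root of the F statistic. The biological coefficient of variation was 0.062. Folds against a group at 0 counts were set against a floor of 3 counts per library, and ratios to 1 to 3 counts were given exact 95% binomial intervals. Both cover counting error only. Where list members had 0 counts in a group, the list's median was also taken with them at that bound, leaving out members at or under the floor in both groups.

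The 28 gene lists held 511 genes, of which 509 were named in the table. They cover PRC2, CBP/P300 and histone acetylation, naive and general pluripotency, formative and primed epiblast, primitive streak and early mesoderm, endoderm, cardiac and muscle, endothelial, blood, neural progenitor, neuron, Hox genes, other textbook Polycomb target regulators, trophoblast, germ cell, 2-cell-like, imprinted genes, fibroblast and mesenchyme, surface ectoderm and epidermis, ERK targets, WNT targets, cell cycle, the p53 pathway, hypoxia and glycolysis, immediate early and heat shock, Y-linked and X inactivation. 5 genes (Cdx1, Eomes, Lef1, Sp5 and T) stand in 2 lists. Each list was tested against all other genes with camera in limma 3.58.1, with a preset correlation of 0.01 and again with an estimated correlation, and p was adjusted over the 28 lists. Counts of list members that passed are given with p adjusted over all genes and adjusted over the list alone.

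The rule for named genes allowed a fixed panel of 24 genes, the 6 genes with the largest change each way in the K19R and wildtype mESC comparisons (4 in the others), and up to 4 called members per list with the smallest adjusted p (2 in the others) where the list had 3 called members or a called camera test. The largest changes needed a mean of 1 CPM in the higher group and, outside the genotype change comparisons, separated replicates, and predicted genes and small RNAs were left out of them. All members of the PRC2, Y-linked and X inactivation lists could be named. Ddx3x, Eif2s3x and Kdm6a were chosen after the Y-linked values were seen, and Apoa2 and Alb in FLAG-WT at day 2 after theirs. A result that the rule allowed is not reported here.

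Alternatives were scaling by RLE size factors or by library totals only, no filter, a stricter filter of 50 counts in 2 libraries, a fold threshold of 2, the replicate number as a block, a fit of only the libraries compared, removal of mitochondrial, ribosomal, small RNA and histone genes, DESeq2 1.42.0 and leaving out each library in turn. Removal of X- and Y-linked genes, and a block with crossed replicate numbers, were added after seeing the data. Leaving out 1 of 2 libraries assumes that the lone sample varies like the other groups. On simulated counts with day 0 means, 5 draws, the test recovered 70.8% of genes changed 1.5-fold, 86% of those changed 2-fold and 99.6% of those changed 4-fold, and 5.58% of its calls were false on average. With day 10 means these shares were 70%, 91.6% and 98%, and 6.9% of the calls were false. Each draw changed few genes, as many up as down, and gave all others the same mean in both lines. The simulation thus did not test the scaling where most genes differ, as at day 10, where 58.4% of genes were called. Its shares of false calls need not hold there. Figures were drawn with matplotlib 3.10.9. A reference annotation of another release was not used here.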

Results

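Gene expression was measured by RNA-seq in mouse embryonic stem cells (mESCs) and in embryoid bodies, the aggregates in which mESCs differentiate in suspension. EED is a core subunit of Polycomb repressive complex 2 (PRC2), which methylates histone H3 at genes it keeps silent. By its title, the series asks what acetylation of EED by the acetyltransferases CBP and P300 does to where PRC2 acts and to mESC differentiation. Knock-in cells carried FLAG-tagged EED of wildtype sequence (FLAG-WT) or the K19R form, in which a lysine is replaced by arginine, a residue that cannot be acetylated. Each was sampled as mESCs in LIF and 2i at day 0 and as embryoid bodies without them at days 2, 6 and 10. A further group held wildtype mESCs grown in LIF alone. There were 9 groups of 2 libraries. Each FLAG-EED library held 20158077 to 28917558 counts and 21614 to 25662 genes with a count. The wildtype mESC libraries held 14190166 and 37375083 counts.

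Eed itself (chromosome 7, 89954654 to 89980983 on GRCm38, minus strand, 3828 exonic bases) fell during differentiation in both lines. FLAG-WT libraries held 178 ± 4.9 CPM of Eed (SD, n = 2) at day 0, 110 ± 1.7 at day 2, 42.7 ± 5.1 at day 6 and 44.8 ± 2.9 at day 10. K19R libraries held 189 ± 14, 79.9 ± 3.1, 44.5 ± 0.17 and 48.5 ± 2.1 CPM. Eed was lower in K19R at day 2 (log2 change -0.46 ± 0.08 SE, edgeR adjusted p = 2.2e-05). It did not pass at day 0 (0.09 ± 0.07, adjusted p = 0.51), day 6 (0.05 ± 0.08, adjusted p = 0.61) or day 10 (0.11 ± 0.08, adjusted p = 0.24). Scaled by library totals only, Eed passed as higher at day 6 (0.41, adjusted p = 0.00016) and day 10 (0.42, adjusted p = 0.00014). Counts per gene do not show the substitution, so the level of Eed does not check the labels.

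On the first principal component, which held 59% of the variance, K19R embryoid bodies lay between FLAG-WT embryoid bodies and day 0 at the later days. FLAG-WT libraries scored -128.3 and -117.8 at day 0, 138.1 and 145.3 at day 6, and 177.1 and 178.6 at day 10. K19R libraries scored -131.2 and -131.5 at day 0, 57.5 and 62.5 at day 6, and 96.5 and 102.5 at day 10. The second component held 14.6%.

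**Figure D1:**
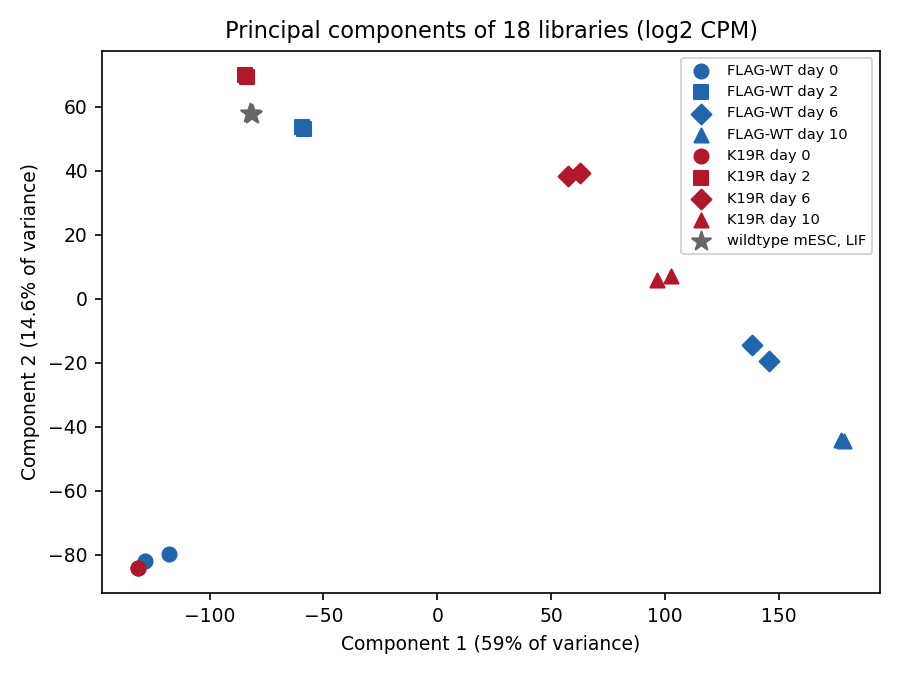
Scores of the 18 libraries on the first and second principal components of log2 CPM, 1 point per library, coloured by line and with the day shown by marker shape. K19R libraries score 57.5 to 102.5 on the first component at days 6 and 10, and FLAG-WT libraries 138.1 to 178.6.

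The FLAG-WT time course asks what changes as cells with wildtype EED leave the stem cell state. The pluripotency regulators Nanog, Sox2 and Pou5f1 fell, and the endoderm regulators Gata4, Gata6 and Foxa2 rose. Nanog (chromosome 6, 122707489 to 122714633) went from 1410 ± 16 CPM (SD, n = 2) at day 0 to 94 ± 0.32 at day 2 and 5.06 ± 1.6 at day 10. Sox2 (chromosome 3, 34650405 to 34652461) went from 534 ± 18 to 2.33 ± 0.34 CPM by day 10 (log2 change -7.84 ± 0.14 SE, edgeR adjusted p = 3.2e-25). Pou5f1 (chromosome 17, 35506018 to 35510772) went from 923 ± 17 to 7.25 ± 0.73 CPM. Gata4 (chromosome 14, 63198922 to 63271692), a regulator of endoderm and heart, rose from 5.15 ± 1.5 to 214 ± 3.8 CPM by day 2 and 400 ± 38 by day 10, and Gata6 (chromosome 18, 11052508 to 11085635) from 2.19 ± 0.47 to 160 ± 0.16 CPM by day 2. Foxa2 rose by 5.75 ± 0.23 log2 at day 2 and 9.10 ± 0.18 at day 10. Fgf5, a marker of the formative epiblast, had 0 counts at day 0 and 3522 at day 2, at least 557-fold higher against a floor of 3 counts per library.

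In FLAG-WT cells, 15 of 22 endoderm members were higher and 3 lower at day 2 (17 and 3 adjusted over the list alone), and 20 were higher and 0 lower at day 10 (20 and 0 over the list alone; camera adjusted p = 1.3e-21, adjusted p = 0.0089 with an estimated correlation). The 3 lower at day 2 were Afp and, named after their values were seen, Apoa2 and Alb, the last at 17 counts at day 0 and 0 at day 2. Afp held 1.78 and 55 CPM in the day 0 replicates 1 and 2 and 2.79 ± 0.048 at day 2. Without day 0 replicate 2, 18 members were higher and 1 lower at day 2, and Afp went from -3.35 to 0.65 (adjusted p = 0.16) and Apoa2 from -2.37 to 0.74 (adjusted p = 0.56). Apoa2 was not called without day 2 replicate 2 either (adjusted p = 0.077). The counts at day 10 were 20 and 0 without either day 0 replicate. Of 18 naive pluripotency members, 17 were lower and 1 higher at day 10, also over the list alone (camera adjusted p = 5e-17, adjusted p = 0.039 with an estimated correlation). For ERK pathway targets, 13 of 17 members were higher and 2 lower at day 2, also over the list alone (camera adjusted p = 1.5e-20, adjusted p = 0.00034 with an estimated correlation). The formative and primed epiblast list had 12 of 14 members higher and 1 lower at day 2, and 5 higher and 9 lower at day 10, both also over the list alone (adjusted p = 0.00034 and 0.062 with an estimated correlation). edgeR called 10709 of 19092 genes at day 2 (5440 higher, 5269 lower), 14528 at day 6 (7069 higher, 7459 lower) and 14876 at day 10 (7065 higher, 7811 lower). With library totals only, the share of calls that were higher went from 48.7% to 37.2% at day 6 and from 47.5% to 36.8% at day 10, and the median of all genes from -0.05 to -0.43 and from -0.12 to -0.53.

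The K19R time course asks the same of cells whose EED lacks that lysine. Nanog fell from 1390 ± 29 to 71.3 ± 1 CPM at day 2 and was 93 ± 7.3 at day 6 and 94.5 ± 10 at day 10 (SD, n = 2). Sox2 went from 527 ± 0.47 CPM at day 0 to 353 ± 24, 104 ± 11 and 103 ± 10 (log2 change at day 10 -2.36 ± 0.09 SE, edgeR adjusted p = 2.9e-18), and Pou5f1 from 964 ± 87 to 89.3 ± 12 at day 10. Gata4 reached 20.4 ± 0.62 CPM at day 2 and 454 ± 22 at day 10, from 5.15 ± 0.086. Fgf5 had 1 count at day 0 and 6690 at day 2, a ratio of 5360 (95% interval 962 to 212000). All 22 endoderm members were higher at day 10, also over the list alone (camera adjusted p = 3.2e-31, adjusted p = 0.021 with an estimated correlation), and 17 of 18 naive pluripotency members were lower, also over the list alone (camera adjusted p = 6e-14, adjusted p = 0.031 with an estimated correlation). edgeR called 10766 genes at day 2 (5436 higher, 5330 lower), 13802 at day 6 (7086 higher, 6716 lower) and 14109 at day 10 (7268 higher, 6841 lower). The larger side at days 6 and 10 turned with the processing. The share higher at day 6, 51.3%, was 49.2% with RLE size factors and 49% with DESeq2, but 51.7% with library totals only. At day 10 it was 51.5%, and 48.6% with RLE size factors, 48.7% with library totals only and 49.6% with DESeq2.

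Day 0 compares K19R with FLAG-WT mESCs before differentiation. Nanog, Sox2 and Pou5f1 did not differ detectably: the log2 change was -0.02 ± 0.10 SE for Nanog (adjusted p = 0.94), -0.02 ± 0.09 for Sox2 (adjusted p = 0.94) and 0.06 ± 0.09 for Pou5f1 (adjusted p = 0.75). The Y-linked genes Ddx3y, Eif2s3y and Uty were higher in K19R: Ddx3y, an RNA helicase gene (chromosome Y, 1260771 to 1286629), stood at 57.7 ± 1.2 against 9.23 ± 0.14 CPM (SD, n = 2), Eif2s3y changed by 2.92 ± 0.11 (adjusted p = 2.7e-15) and Uty by 2.94 ± 0.18 (adjusted p = 1.5e-11). Xist, the RNA that coats the inactive X chromosome (chromosome X, 103460366 to 103483254), was lower (2.5 ± 0.17 against 5.06 ± 0.5 CPM, adjusted p = 0.00024). H19, an imprinted RNA, fell by 2.58 ± 0.14 log2 (adjusted p = 1.6e-12), from 138 ± 48 to 23.2 ± 0.56 CPM. FLAG-WT replicates 1 and 2 held 104 and 172 CPM of H19, and K19R replicates 1 and 2 held 22.8 and 23.6.

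At day 0, edgeR called 2003 of 19092 genes, 1052 higher and 951 lower in K19R, and 329 of them changed at least 2-fold. The share higher was 52.5%, and it was 59.3% with RLE size factors and 42.6% with library totals only, so the larger side turned with the scaling. The test called 4014 genes in a fit of the 4 day 0 libraries alone. The count was 880 without FLAG-WT replicate 1, 844 without FLAG-WT replicate 2, 889 without K19R replicate 1 and 957 without K19R replicate 2. Of the 5 measured Y-linked genes, 4 were higher and 1 did not pass, and all 5 were higher when adjusted over the list alone (camera adjusted p = 1.3e-44, adjusted p = 5.7e-05 with an estimated correlation). Kdm5d had 9 counts against 1, a ratio of 9.17 (95% interval 1.27 to 402). Zfy1 (2.64 ± 0.74, adjusted p = 0.023) was not called without FLAG-WT replicate 1 (2.67), FLAG-WT replicate 2 (2.61) or K19R replicate 1 (1.95). It was not called with DESeq2 either (2.71), which gave it no adjusted p. Of 10 measured 2-cell-like members, 4 were lower and 6 did not pass, and 5 were lower over the list alone (camera adjusted p = 4.5e-05, adjusted p = 0.035 with an estimated correlation). They included Zscan4d (-0.92 ± 0.15) and Zscan4c (-0.59 ± 0.11). Of 18 germ cell members, 5 were lower, 1 higher and 12 did not pass, and 5 were lower and 3 higher over the list alone (camera adjusted p = 0.0014, adjusted p = 0.26 with an estimated correlation). Dazl fell by 1.58 ± 0.10 and Ddx4 by 1.09 ± 0.16. Of 20 hypoxia and glycolysis members, 7 were higher and 13 did not pass, and 8 were higher and 1 lower over the list alone (camera adjusted p = 4.9e-05, adjusted p = 0.24 with an estimated correlation). Bnip3 rose by 1.13 ± 0.12, Pfkl by 0.60 ± 0.07 and Ldha by 0.52 ± 0.07.

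At day 0, endoderm transcripts were unevenly spread over the FLAG-WT libraries. Afp, the fetal serum protein alpha-fetoprotein (chromosome 5, 90490737 to 90508907), stood at 1.78 CPM in FLAG-WT replicate 1 and at 55 in replicate 2. Of 22 endoderm members, 10 were lower in K19R, 1 was higher and 11 did not pass, and 12 were lower and 1 higher over the list alone (camera adjusted p = 1.8e-05, adjusted p = 0.34 with an estimated correlation). Without FLAG-WT replicate 2 the list was not called (camera adjusted p = 0.67), 2 of the 10 members were called, and Afp went from -7.08 ± 1.11 to -3.08 ± 0.63 (adjusted p = 0.0039). Ttr, with 230 counts in FLAG-WT and 1 in K19R, had a ratio of 226 (95% interval 40.1 to 8950), and without that library its log2 change went from -7.49 to -2.33 ± 1.41 (adjusted p = 0.43). Apoa1 had a ratio of 74.6 (95% interval 25.2 to 364) and went from -6.10 to -2.33 ± 0.77 (adjusted p = 0.11). Apoa2 and Fgb, at 0 counts in K19R, were at least 8.99-fold and 8.5-fold higher in FLAG-WT. FLAG-WT replicates 1 and 2 held 3 and 52 counts of Apoa2 and 2 and 50 of Fgb, and without replicate 2 the fitted changes, which are no bounds, went from -7.77 to -4.65 and from -7.69 to -4.10 (adjusted p = 0.22 and 0.25). Among 13 PRC2 members, Jarid2 (0.31 ± 0.07, adjusted p = 0.0038) and Ezh1 (0.26 ± 0.07, adjusted p = 0.023) were higher and 11 did not pass, also over the list alone (camera adjusted p = 0.82). Jarid2 was not called without FLAG-WT replicate 1 (adjusted p = 0.053), and Ezh1 was not called when any 1 of the 4 day 0 libraries was left out (adjusted p from 0.11 to 0.16). Suz12 (-0.13 ± 0.08, adjusted p = 0.32) passed as lower in a fit of the 4 day 0 libraries alone (-0.12, adjusted p = 0.039). Gata6 (-0.75 ± 0.21, adjusted p = 0.021) was not called without FLAG-WT replicate 1 (adjusted p = 0.32), without K19R replicate 2 (adjusted p = 0.19) or in a fit of the 4 day 0 libraries alone (adjusted p = 0.056).

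**Figure D2:**
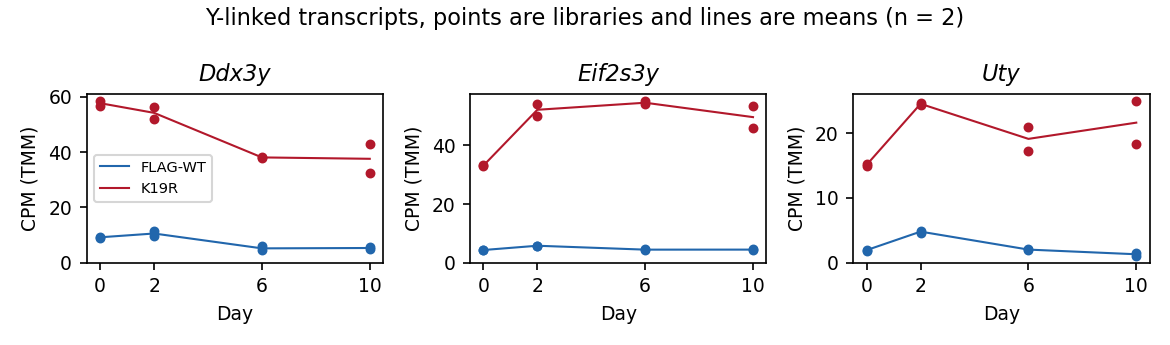
Levels of Ddx3y, Eif2s3y and Uty (CPM, linear axis from 0) by day in FLAG-WT and K19R, with 1 point per library and lines through the means of 2 libraries. FLAG-WT libraries hold 5.23 to 10.6 CPM of Ddx3y as group means and K19R libraries 37.6 to 57.7.

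Day 2 compares the lines early in differentiation. The endoderm regulators Gata4, Gata6 and Foxa2, which rose in FLAG-WT, were lower in K19R: Gata4 stood at 20.4 ± 0.62 against 214 ± 3.8 CPM (SD, n = 2; log2 change -3.39 ± 0.10 SE, adjusted p = 1.5e-19), Gata6 at 24.7 ± 1.6 against 160 ± 0.16 CPM, and Foxa2 at 2.44 ± 0.54 against 16.5 ± 0.62 CPM. Sox7 fell by 3.60 ± 0.11 and Sox17 by 2.05 ± 0.14. The naive pluripotency factors Klf4 (chromosome 4, 55527143 to 55532466), at 10.4 ± 0.9 against 50.4 ± 0.75 CPM, Tbx3 (-2.49 ± 0.09) and Klf5 (-2.22 ± 0.08) were lower as well, while 4 of 18 members of that list were higher and its call was lost with an estimated correlation (adjusted p = 0.12). The formative epiblast genes Pou3f1 (1.71 ± 0.09) and Fgf5 were higher, the latter at 111 ± 9.1 against 67.6 ± 0.92 CPM. Some members of the immediate early and heat shock list were lower: Chac1 stood at 2.69 ± 0.18 against 72.4 ± 3.4 CPM, and Trib3 fell by 3.02 ± 0.11 and Atf3 by 3.12 ± 0.17.

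Of 22 measured endoderm members at day 2, 18 were lower and 4 did not pass, and 18 were lower when adjusted over the list alone (camera adjusted p = 1.9e-35, adjusted p = 0.013 with an estimated correlation). Of those that did not pass, Afp (0.79 ± 0.83, adjusted p = 0.47) passed as higher with no filter (adjusted p = 4.7e-07) and in a fit of the 4 day 2 libraries alone (adjusted p = 0.028). Its SE was 0.11 with no filter and 0.29 in that fit, so the spread fitted for Afp depended on the genes and libraries kept. Naive pluripotency had 12 of 18 members lower and 4 higher, also over the list alone (camera adjusted p = 1.9e-09, adjusted p = 0.12 with an estimated correlation). In the formative and primed epiblast list 12 of 14 members were higher and 2 did not pass, and 13 were higher over the list alone (camera adjusted p = 3.6e-08, adjusted p = 0.0073 with an estimated correlation). Primitive streak and early mesoderm genes were lower in 7 and higher in 4 of 16, and in 8 and 4 over the list alone (camera adjusted p = 0.00037, adjusted p = 0.032 with an estimated correlation), with Pdgfra at -3.74 ± 0.09 and Eomes at -1.37 ± 0.14. The 2-cell-like list, lower at day 0, had 9 of 10 members higher and all 10 over the list alone (camera adjusted p = 5.5e-05, adjusted p = 0.023 with an estimated correlation), with Zscan4c at 1.34 ± 0.11 and Usp17lc at 1.83 ± 0.25. Hypoxia and glycolysis genes were higher in 11 and lower in 5 of 20, also over the list alone (camera adjusted p = 0.0024, adjusted p = 0.23 with an estimated correlation). Its members moved apart: the glycolytic enzyme gene Ldha rose by 1.69 ± 0.07 and the glucose transporter gene Slc2a1 by 1.92 ± 0.08, while the growth factor gene Vegfa fell by 3.37 ± 0.08, from 82.3 ± 4.9 to 7.94 ± 0.43 CPM, and Slc2a3 by 2.47 ± 0.09. Immediate early and heat shock genes were higher in 7 and lower in 7 of 19, also over the list alone (camera adjusted p = 0.0044 for lower, adjusted p = 0.42 with an estimated correlation). Endothelial genes were higher in 6 and lower in 2 of 13, and in 7 and 3 over the list alone (camera adjusted p = 0.023, adjusted p = 0.25 with an estimated correlation). That call was lost without FLAG-WT replicate 2 (camera adjusted p = 0.053) or K19R replicate 1 (camera adjusted p = 0.08).

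PRC2 genes at day 2 were lower in 5 of 13 members and higher in 0, also over the list alone, and the list was not called (camera adjusted p = 0.13, adjusted p = 0.23 with an estimated correlation). Rbbp7 fell by 0.83 ± 0.08, Epop by 0.59 ± 0.07, Phf19 by 0.60 ± 0.15 and Ezh1 by 0.46 ± 0.07, and Eed was the remaining one. Ezh2 (0.09 ± 0.07, adjusted p = 0.29) and Suz12 (0.05 ± 0.08, adjusted p = 0.62) did not pass. Sox2 (0.06 ± 0.09, adjusted p = 0.58) and Pou5f1 (0.07 ± 0.10, adjusted p = 0.61) did not pass either, and Nanog fell by 0.40 ± 0.10 (adjusted p = 0.0027). Ddx3y stood at 54.2 ± 3 against 10.6 ± 1.2 CPM and Xist at 4.82 ± 0.53 against 20.1 ± 1.2 CPM. edgeR called 7973 genes, 3818 higher and 4155 lower, and 2215 changed at least 2-fold. The share higher, 47.9%, was 50.9% with RLE size factors and 51.1% with a stricter filter on low counts.

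**Figure D3:**
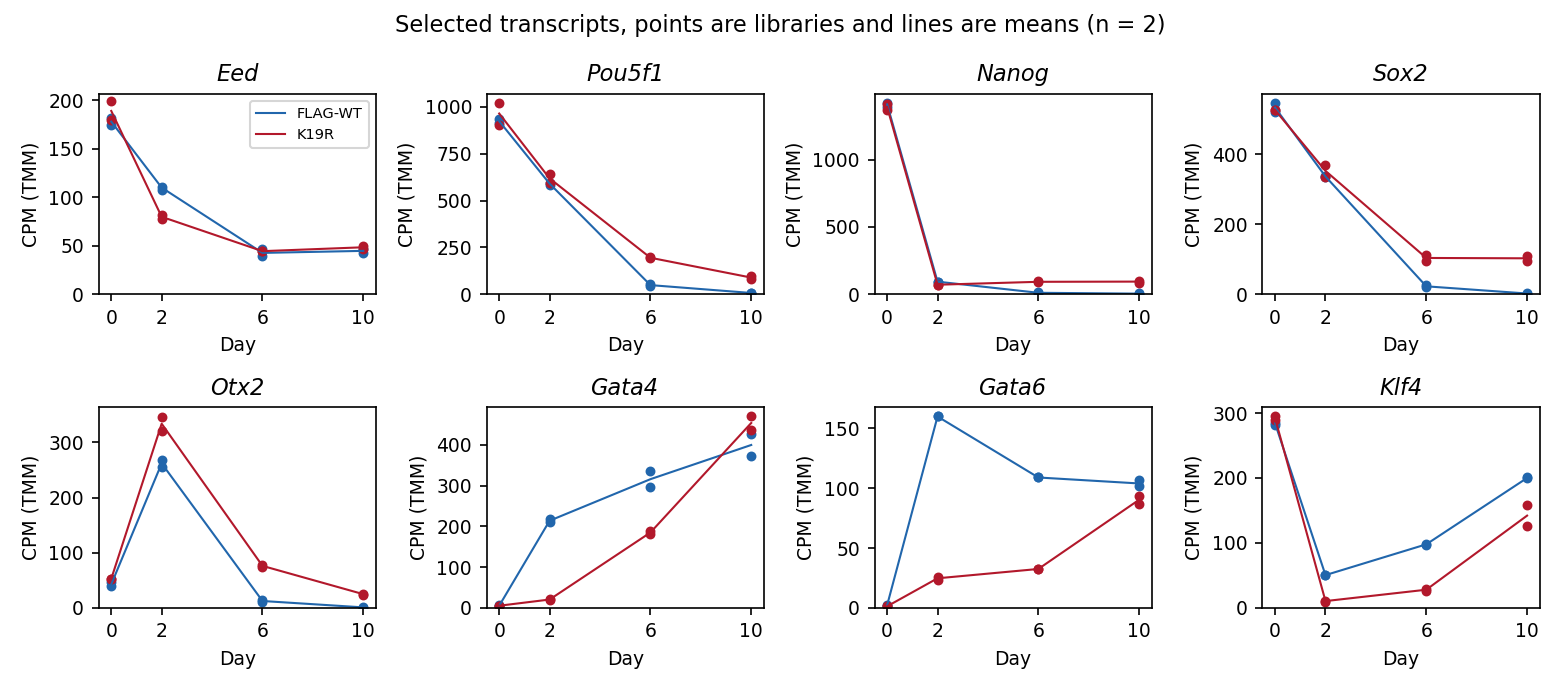
Levels of Eed, Pou5f1, Nanog, Sox2, Otx2, Gata4, Gata6 and Klf4 (CPM, linear axis from 0) by day in FLAG-WT and K19R, with 1 point per library and lines through the means of 2 libraries. Gata4 is at 20.4 CPM in K19R and 214 CPM in FLAG-WT at day 2, and Sox2 at 103 and 2.33 CPM at day 10.

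Day 6 asks which differences are present once FLAG-WT cells have lost most pluripotency transcripts. Nanog, Sox2 and Pou5f1 were higher in K19R: Nanog stood at 93 ± 7.3 against 11.5 ± 3.1 CPM (SD, n = 2; log2 change 2.99 ± 0.13 SE, adjusted p = 3.4e-16), Sox2 at 104 ± 11 against 22.9 ± 4.2 CPM and Pou5f1 at 195 ± 2.9 against 49.2 ± 10 CPM. Otx2, an epiblast and anterior regulator (chromosome 14, 48657677 to 48673819), stood at 76.1 ± 3.2 against 12.4 ± 2.1 CPM, and Zic2 rose by 3.96 ± 0.15. The endoderm genes Gata6, at 32.5 ± 0.48 against 109 ± 0.21 CPM, Foxa2, at 42.7 ± 1.1 against 130 ± 9.8 CPM, and Apoa2 (-3.03 ± 0.16) were lower. Stmn2 (3.78 ± 0.14) and Gap43 (4.55 ± 0.23) of the neuron list and Col1a1 (3.75 ± 0.28) and Col6a1 (3.98 ± 0.30) of the fibroblast and mesenchyme list were higher. Of the 5 naive factors that were lower, Klf4 stood at 27.9 ± 2.5 against 97.8 ± 1.6 CPM and Klf2 changed by -1.73 ± 0.09. The calls of the endoderm, neuron, fibroblast and naive lists at day 6 were lost with an estimated correlation (adjusted p = 0.15, 0.11, 0.23 and 0.35).

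Of 14 formative and primed epiblast members at day 6, 13 were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 4.7e-09, adjusted p = 0.0047 with an estimated correlation). Naive pluripotency had 12 of 18 higher and 5 lower (camera adjusted p = 0.0046, adjusted p = 0.35 with an estimated correlation) and general pluripotency 8 of 12 higher and 2 lower (camera adjusted p = 6.7e-05, adjusted p = 0.11 with an estimated correlation), both also over the list alone. Endoderm had 19 of 22 lower and 0 higher, also over the list alone (camera adjusted p = 1.4e-10, adjusted p = 0.15 with an estimated correlation). Neuron genes were higher in 10 and lower in 5 of 16 (camera adjusted p = 0.00013, adjusted p = 0.11 with an estimated correlation), and fibroblast and mesenchyme genes higher in 8 and lower in 2 of 14 (camera adjusted p = 0.018, adjusted p = 0.23 with an estimated correlation), both also over the list alone. ERK targets were lower in 11 and higher in 1 of 17 (camera adjusted p = 0.0046, adjusted p = 0.11 with an estimated correlation), with Fos at -1.54 ± 0.09 and Egr1 at -1.34 ± 0.09. Immediate early and heat shock genes were lower in 13 and higher in 3 of 19 (camera adjusted p = 3.8e-05, adjusted p = 0.25 with an estimated correlation), with Atf3 at -2.02 ± 0.09 and Junb at -1.62 ± 0.08. Both sets of counts were the same over the list alone. Cell cycle genes were higher in 10 and lower in 3 of 20, also over the list alone (camera adjusted p = 0.017, adjusted p = 0.25 with an estimated correlation), with Mcm3 at 1.00 ± 0.07. WNT targets were higher in 9 and lower in 2 of 14, also over the list alone (camera adjusted p = 0.049, adjusted p = 0.32 with an estimated correlation). The WNT call was lost with the replicate block (camera adjusted p = 0.051) and without FLAG-WT replicate 2 (0.068) or K19R replicate 2 (0.065).

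Hox genes, classical PRC2 targets, were lower in 15 of 30 members at day 6 and higher in 0, also over the list alone, and the list was not called (camera adjusted p = 0.14, adjusted p = 0.41 with an estimated correlation). Hoxb8 fell by 2.05 ± 0.39 and Hoxb4 by 1.28 ± 0.21. PRC2 genes were lower in 7 and higher in 4 of 13, also over the list alone (camera adjusted p = 0.24), and their median of -0.25 turned to 0.11 with library totals only. Epop, at 114 ± 4 against 335 ± 18 CPM, and Ezh2 (-0.57 ± 0.07) were lower, and Phf19 (2.00 ± 0.22) was higher. Suz12 (-0.25 ± 0.08, adjusted p = 0.0079) was not called without FLAG-WT replicate 1 (adjusted p = 0.062), without K19R replicate 2 (adjusted p = 0.09) or with the stricter filter (adjusted p = 0.058). Its change was 0.11 with library totals only. Afp stood at 2420 ± 180 against 6360 ± 210 CPM (adjusted p = 0.011, but 0.073 without K19R replicate 2, 0.058 with library totals only and 0.12 with DESeq2). The Afp fits named here all kept FLAG-WT day 0 replicate 2, which enters the shared spread, so its lost calls need not come from the day 6 libraries. Ddx3y stood at 38.1 ± 0.41 against 5.23 ± 1 CPM and Xist at 3.09 ± 0.17 against 28.8 ± 0.61 CPM. edgeR called 11171 genes, 5429 higher and 5742 lower, and 4690 changed at least 2-fold. With library totals only the share higher went from 48.6% to 72.9%, as the median of all genes went from 0.02 to 0.38. Relative to the median of all genes, the list medians were 1.87 for formative and primed epiblast, 1.14 for naive pluripotency and -1.47 for endoderm.

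Day 10 is the last time point. Sox2 stood at 103 ± 10 CPM in K19R against 2.33 ± 0.34 in FLAG-WT (SD, n = 2; log2 change 5.47 ± 0.14 SE, adjusted p = 3.9e-20), Nanog at 94.5 ± 10 against 5.06 ± 1.6 CPM, Pou5f1 at 89.3 ± 12 against 7.25 ± 0.73 CPM and Otx2 at 24.8 ± 1.6 against 0.823 ± 0.43 CPM. Brachyury (T), a primitive streak regulator, had 235 counts in K19R and 0 in FLAG-WT, at least 30.5-fold higher against a floor of 3 counts per library. The mesenchymal genes Vim, Col1a1 and Postn were higher, Vim at 187 ± 5.4 against 12.5 ± 1.4 CPM, Col1a1 by 5.23 ± 0.34, and Postn at 968 counts against 1, a ratio of 753 (95% interval 135 to 29800). The ERK targets Fos, at 17.7 ± 1.6 against 172 ± 11 CPM, Dusp5 (-2.99 ± 0.10) and Myc (-2.17 ± 0.09) were lower. The endoderm regulators Gata4, at 454 ± 22 against 400 ± 38 CPM (adjusted p = 0.062), and Sox17, at 131 ± 1.8 against 113 ± 25 CPM (adjusted p = 0.071), did not pass. Both passed as higher without FLAG-WT replicate 1 (0.28, adjusted p = 0.013, and 0.46, adjusted p = 3e-04), with no filter (adjusted p = 0.013 and 0.015) and with library totals only (adjusted p = 2.2e-05 and 2e-04).

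Of 14 formative and primed epiblast members at day 10, 11 were higher and 3 did not pass, also adjusted over the list alone (camera adjusted p = 1.8e-14, adjusted p = 0.0012 with an estimated correlation). Naive pluripotency had 14 of 18 higher and 4 lower (camera adjusted p = 1.3e-13, adjusted p = 0.039 with an estimated correlation) and general pluripotency 10 of 12 higher and 0 lower (camera adjusted p = 4.9e-15, adjusted p = 0.0067 with an estimated correlation), both also over the list alone. Esrrb rose by 4.72 ± 0.17, and Klf4 changed by -0.50 ± 0.08 (adjusted p = 7.3e-06), a call that ended with library totals only (-0.19, adjusted p = 0.051). Primitive streak and early mesoderm genes were higher in 10 and lower in 2 of 16 (camera adjusted p = 0.00041, adjusted p = 0.035 with an estimated correlation), with Wnt3 at 3.46 ± 0.29 and Eomes at 1.87 ± 0.16. The 2-cell-like list had 9 of 10 higher and 0 lower (camera adjusted p = 0.00041, adjusted p = 0.035 with an estimated correlation), with Zscan4c at 3.52 ± 0.21. CBP/P300 and histone acetylation genes had 9 of 10 higher and 1 lower (camera adjusted p = 0.0022, adjusted p = 0.035 with an estimated correlation), with Crebbp, which encodes CBP, at 0.94 ± 0.11, Kat2b at 1.21 ± 0.11 and Hdac1 at 1.01 ± 0.07. The counts of these 3 lists were the same over the list alone. Fibroblast and mesenchyme genes were higher in 8 and lower in 4 of 14, and in 9 and 4 over the list alone (camera adjusted p = 0.00016, adjusted p = 0.036 with an estimated correlation). Neuron genes were higher in 11 and lower in 3 of 16, and in 12 and 3 over the list alone (camera adjusted p = 0.003, adjusted p = 0.17 with an estimated correlation), with Stmn2 at 5.28 ± 0.21. WNT targets were higher in 9 and lower in 2 of 14, and in 10 and 2 over the list alone (camera adjusted p = 0.03, adjusted p = 0.23 with an estimated correlation), a call lost without FLAG-WT replicate 1 (camera adjusted p = 0.11).

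ERK targets at day 10 were lower in 11 and higher in 5 of 17 (camera adjusted p = 8.2e-09, adjusted p = 0.0057 with an estimated correlation), and immediate early and heat shock genes lower in 15 and higher in 3 of 19 (camera adjusted p = 3.5e-12, adjusted p = 0.045 with an estimated correlation), both also over the list alone. Fosb fell by 3.62 ± 0.15, Atf3 by 2.66 ± 0.09 and the small heat shock gene Hspb1 by 2.19 ± 0.09. Surface ectoderm and epidermis genes were lower in 8 and higher in 3 of 13, and in 8 and 4 over the list alone (camera adjusted p = 0.00019, adjusted p = 0.058 with an estimated correlation), with Perp at -2.62 ± 0.08, Cldn4 at -1.95 ± 0.09 and Cdh1, the E-cadherin gene, at -1.13 ± 0.07. The p53 pathway list had 12 of 18 lower and 3 higher, and 13 and 3 over the list alone (camera adjusted p = 0.00035, adjusted p = 0.15 with an estimated correlation), with Pmaip1 at -2.17 ± 0.10 and Bbc3 at -1.41 ± 0.09, both encoding inducers of cell death. Hypoxia and glycolysis genes were lower in 11 and higher in 6 of 20, also over the list alone (camera adjusted p = 0.011, adjusted p = 0.23 with an estimated correlation), a call lost without K19R replicate 1 (camera adjusted p = 0.05).

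Endoderm members at day 10 went both ways, 5 higher and 9 lower of 22, also over the list alone (camera adjusted p = 0.45, adjusted p = 0.79 with an estimated correlation), and their median of -0.10 turned to 0.20 with library totals only. Sox7 was higher (1.91 ± 0.13) and Foxa2 (-0.93 ± 0.09) and Apoa4 (-1.41 ± 0.12) were lower. Gata6 (-0.21 ± 0.07, adjusted p = 0.02) was not called without FLAG-WT replicate 1 (adjusted p = 0.1), without K19R replicate 2 (adjusted p = 0.15) or with no filter (adjusted p = 0.11). Its change was 0.10 with library totals only. Afp (-1.11 ± 0.45, adjusted p = 0.038) was not called when any 1 of the 4 day 10 libraries was left out (adjusted p from 0.065 to 0.16), with library totals only (0.13), with the stricter filter (0.055) or with DESeq2 (0.2). These Afp fits all kept FLAG-WT day 0 replicate 2, which enters the shared spread, so its lost calls need not come from the day 10 libraries. PRC2 genes were higher in 3 and lower in 4 of 13, also over the list alone (camera adjusted p = 0.74), and their median of 0.04 was -0.03 with RLE size factors. The mean of that list was -0.02 and its test in the lower direction. Mtf2 rose by 0.74 ± 0.10 and Lcor fell by 1.08 ± 0.11. Ezh2 (0.08 ± 0.07, adjusted p = 0.31) and Suz12 (-0.13 ± 0.08, adjusted p = 0.16) did not pass. Ezh2 passed as higher with library totals only (0.39, adjusted p = 1.8e-05). Suz12 passed as lower with RLE size factors (adjusted p = 0.036), with DESeq2 (adjusted p = 0.038) and without K19R replicate 2 (-0.27, adjusted p = 0.0059). Among X inactivation genes 1 was higher and 3 lower of 5, also over the list alone (camera adjusted p = 0.0022, adjusted p = 0.11 with an estimated correlation), with Xist at 1.68 ± 0.1 against 31.6 ± 3.2 CPM and Rlim, an activator of Xist, at -1.38 ± 0.07. Ddx3y stood at 37.6 ± 7.3 against 5.36 ± 0.62 CPM. edgeR called 11142 genes, 6336 higher and 4806 lower, and 4754 changed at least 2-fold. With library totals only the share higher went from 56.9% to 77%, as the median of all genes went from 0.13 to 0.44. Relative to the median of all genes, the list medians were 2.97 for formative and primed epiblast, 2.31 for naive pluripotency, 1.36 for general pluripotency and -0.88 for ERK targets.

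**Figure D4:**
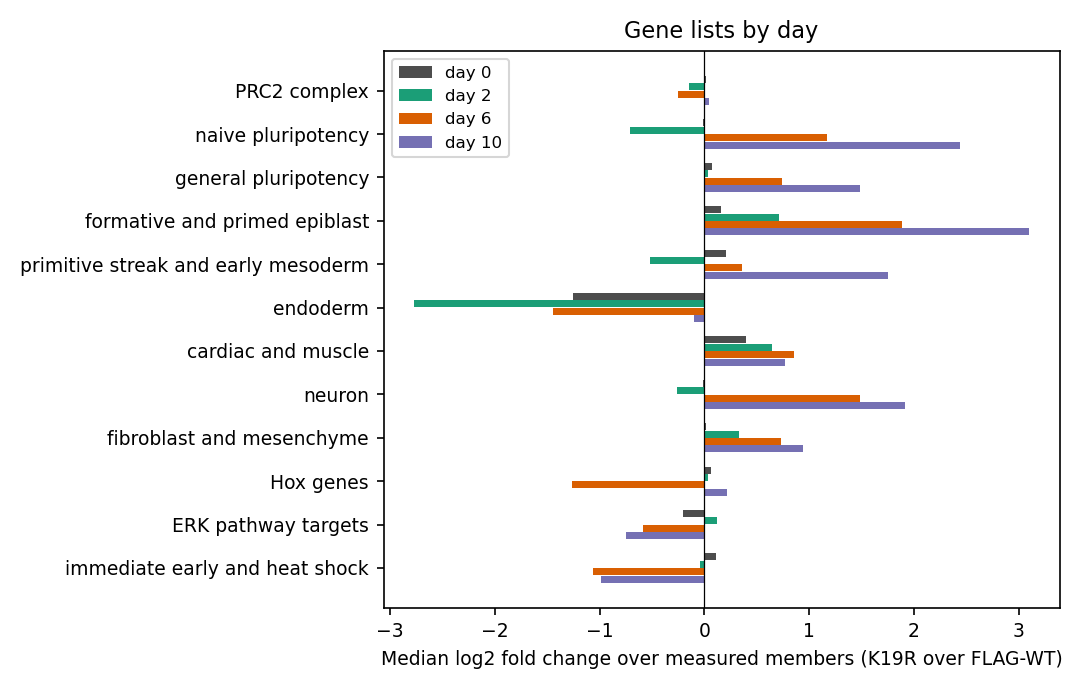
Median log2 change of K19R over FLAG-WT over the measured members of 12 gene lists, with 1 bar per list and day (TMM scaling, 2 libraries per group, members at 0 counts at their bound). The formative and primed epiblast list stands at 0.16, 0.71, 1.89 and 3.1 at days 0, 2, 6 and 10, while PRC2 at days 0, 6 and 10, endoderm at day 10, and naive pluripotency, neuron and fibroblast and mesenchyme at day 0 change sign or reach 0 under another scaling.

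Whether the genotype difference itself changed from day 0 was tested as an interaction. edgeR called 5182 genes for day 2 (2434 higher, 2748 lower), 8488 for day 6 (4219 higher, 4269 lower) and 8584 for day 10 (4991 higher, 3593 lower). Nanog differed by 3.01 ± 0.16 SE at day 6 and 4.24 ± 0.18 at day 10 (adjusted p = 1.3e-13 and 9.4e-16), Sox2 by 2.19 ± 0.13 and 5.48 ± 0.17, and Gata4 by -3.39 ± 0.19 at day 2 (adjusted p = 3.5e-13). With library totals only the share higher went from 49.7% to 76.9% for day 6 and from 58.1% to 80.3% for day 10, as the median of all genes went from 0.05 to 0.43 and from 0.16 to 0.49. Genes called in the same direction at different days, which share no libraries, numbered 3319 higher and 3196 lower for days 6 and 10, where independent lists of those sizes would share 1802 and 1445. For days 2 and 6 the shared calls numbered 1805 higher and 2300 lower (1086 and 1250 for independent lists), and for days 0 and 2, 389 and 386 (210 and 207). For days further apart, days 2 and 10 shared 1654 and 1547 (1267 and 1046). Days 0 and 6 shared 376 and 450 (299 and 286), and days 0 and 10 shared 420 and 320 (349 and 239).

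The wildtype mESCs, grown in LIF alone, were compared with FLAG-WT mESCs in LIF and 2i. The medium, the knock-in and the table differ together here, and their effects cannot be told apart. Among ERK targets, a pathway that the MEK inhibitor of 2i blocks, Spry4, Etv4 and Egr1 were higher in the wildtype mESCs: Spry4, a feedback inhibitor of the pathway, stood at 129 ± 3 against 1.06 ± 0.21 CPM (SD, n = 2), Etv4 rose by 5.82 ± 0.14 SE and Egr1 by 5.77 ± 0.18. Nanog (-1.93 ± 0.10) and Tbx3 (-2.79 ± 0.09) were lower, and the DNA methyltransferase genes Dnmt3b (2.31 ± 0.08) and Dnmt3a (1.44 ± 0.07) were higher. The Polycomb targets Meis2, at 0.919 ± 0.2 against 69.3 ± 2.1 CPM, Hoxd13 (-3.67 ± 0.22) and Gata3 (-6.32 ± 0.22) were lower. The calls of the Hox list and of the other Polycomb target regulators were lost with an estimated correlation (adjusted p = 0.33 and 0.19). Epop, a PRC2-associated gene, stood at 149 ± 2 against 1130 ± 13 CPM.

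In that comparison 12 of 17 ERK targets were higher and 1 lower (camera adjusted p = 1.5e-16, adjusted p = 0.0034 with an estimated correlation), and 18 of 20 hypoxia and glycolysis genes were higher and 2 lower (camera adjusted p = 1e-24, adjusted p = 0.0029 with an estimated correlation), with Pdk1 at 5.57 ± 0.12 and Egln3 at 5.68 ± 0.13. Of 30 Hox genes 23 were lower and 0 higher (camera adjusted p = 0.00091, adjusted p = 0.33 with an estimated correlation), and of 41 other Polycomb target regulators 25 were lower and 3 higher (camera adjusted p = 0.002, adjusted p = 0.19 with an estimated correlation). The counts of these 4 lists were the same over the list alone. Eed was higher (211 ± 4 against 180 ± 4.9 CPM in the joint fit, log2 change 0.23 ± 0.07, adjusted p = 0.0061), a call lost without FLAG-WT replicate 2 (adjusted p = 0.06), without wildtype replicate 2 (adjusted p = 0.052) or with no filter (adjusted p = 0.081). Ezh2 rose by 0.87 ± 0.06 and Suz12 fell by 0.45 ± 0.08, and the PRC2 list had 8 of 13 members higher and 5 lower, also over the list alone (camera adjusted p = 0.87, median 0.35, mean -0.07, test in the lower direction). Suz12, like Ezh1 and Epop, lies on chromosome 11, where 885 genes had a median of -0.407 in this comparison. The fall of Suz12 was therefore close to that of its chromosome, and the cause was not tested. Afp had 2 counts against 1434, a ratio of 820 in favour of FLAG-WT (95% interval 227 to 6780), and its log2 change went from -9.47 to -5.46 without FLAG-WT replicate 2. All 6 measured Y-linked genes were higher, also over the list alone (camera adjusted p = 2e-09, adjusted p = 0.0088 with an estimated correlation), with Ddx3y at 110 ± 16 CPM. edgeR called 12519 of 19296 genes, 6251 higher and 6268 lower.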

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

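The interaction tests, the panel and the settings named beside them were planned. The tests of explanations in the last 3 paragraphs were chosen after the results they bear on had been seen, except the count of reads on the X-linked copies, which was set before that count was made. First tests of Y chromosome loss and of the genotype at day 0 restated their patterns, and a first test of a delay used a list that rose and then fell in FLAG-WT, and these were set aside. A first form of the scaling test, the list median less that of all genes, gives the same value under every scaling by construction and was set aside too.

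The genotype difference (K19R over FLAG-WT) changed between day 0 and each later day, by edgeR's test of the interaction, for 5182 genes at day 2, 8488 at day 6 and 8584 at day 10 of 19092. Of the 24 panel genes, 10 passed at day 2. These were Klf4 (-2.32, adjusted p = 2.3e-13), Gata4 (-3.39, adjusted p = 3.5e-13), Gata6 (-1.94, adjusted p = 7.4e-07), Eomes (-1.63, adjusted p = 9.2e-05), Eed (-0.54, adjusted p = 0.0003), Sox17 (-1.34, adjusted p = 0.0098), Jarid2 (-0.33, adjusted p = 0.011), Nanog (-0.38, adjusted p = 0.048), Kdr (1.80, adjusted p = 2.8e-05) and Afp (7.88, adjusted p = 0.00029). Jarid2 was not called without K19R day 2 replicate 2 (adjusted p = 0.053), nor Sox17 without K19R day 0 replicate 2 (adjusted p = 0.094). Nanog was not called when any 1 of the 8 libraries compared was left out (adjusted p from 0.071 to 0.12), with library totals only (0.064), with the stricter filter (0.069) or with DESeq2 (0.21). Without FLAG-WT day 0 replicate 2, Afp went to 3.87 (adjusted p = 0.00012) and Foxa2 passed as well (-2.76, adjusted p = 0.045).

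At day 6 the panel genes that passed were Pou5f1 (1.91, adjusted p = 3.5e-11), Nanog (3.01, adjusted p = 1.3e-13), Sox2 (2.19, adjusted p = 1.3e-12), Klf4 (-1.86, adjusted p = 3.1e-12), Ezh2 (-0.62, adjusted p = 6e-06), Tubb3 (1.83, adjusted p = 5.2e-08), Gata4 (-0.77, adjusted p = 0.001), Gata6 (-1, adjusted p = 0.00096), Afp (5.69, adjusted p = 0.0014), Brachyury (T, 3.61, adjusted p = 0.0088) and Nkx2-5 (-2.08, adjusted p = 0.016). Brachyury went to 6.16 without FLAG-WT day 6 replicate 1 and was not called without FLAG-WT day 6 replicate 2 (adjusted p = 0.052). Gata4 went to -0.50 (adjusted p = 0.024) without FLAG-WT day 0 replicate 1 and was not called with library totals only (-0.38, adjusted p = 0.086). Without FLAG-WT day 0 replicate 2, Afp went to 1.69 (adjusted p = 0.048). Gata6 was not called without K19R day 0 replicate 1 (adjusted p = 0.059). Nkx2-5 was not called without FLAG-WT day 6 replicate 1 (adjusted p = 0.19), K19R day 0 replicate 1 (adjusted p = 0.053) or K19R day 6 replicate 1 (adjusted p = 0.071). With library totals only, as the median of all genes went from 0.05 to 0.43, Eed (0.35, adjusted p = 0.012), Suz12 (0.27, adjusted p = 0.037), Jarid2 (0.46, adjusted p = 0.00021), Tnnt2 (1.66, adjusted p = 0.015) and Sox1 (1.6, adjusted p = 0.041) passed as well. Tnnt2 also passed without FLAG-WT day 6 replicate 1 (1.86, adjusted p = 0.04) and Sox1 without K19R day 6 replicate 1 (1.74, adjusted p = 0.038).

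At day 10 the panel genes that passed were Pou5f1 (3.56, adjusted p = 7.4e-15), Nanog (4.24, adjusted p = 9.4e-16), Sox2 (5.48, adjusted p = 5.4e-18), Klf4 (-0.54, adjusted p = 0.00028), Eomes (1.61, adjusted p = 8.8e-05), Tubb3 (2.05, adjusted p = 1.4e-08), Sox1 (2.44, adjusted p = 0.0013), Nkx2-5 (2.26, adjusted p = 0.0056), Kdr (-1.10, adjusted p = 0.0028), Gata1 (-1.41, adjusted p = 0.014), Pax6 (-1.17, adjusted p = 0.016), Sox17 (0.92, adjusted p = 0.033), Gata6 (0.54, adjusted p = 0.049), Afp (5.97, adjusted p = 0.00079) and Brachyury (T, 8.76, adjusted p = 3.7e-06). The last value is a fitted one, as FLAG-WT had 0 counts of Brachyury at day 10. Afp went to 1.97 (adjusted p = 0.02) without FLAG-WT day 0 replicate 2. Gata6 went to 0.31 (adjusted p = 0.39) without FLAG-WT day 0 replicate 1, and was not called without FLAG-WT day 10 replicate 2 (0.082), K19R day 0 replicate 2 (0.24) or K19R day 10 replicate 1 (0.091). It was not called either with RLE size factors (0.098), no filter (0.087), the stricter filter (0.05), only the libraries compared (0.072) or DESeq2 (0.13). Sox17 was not called without FLAG-WT day 0 replicate 1 (0.067), FLAG-WT day 0 replicate 2 (0.092), FLAG-WT day 10 replicate 2 (0.051) or K19R day 0 replicate 1 (0.19). Kdr was not called without K19R day 0 replicate 1 (0.051), and Gata1 was not called without FLAG-WT day 10 replicate 2 (0.074) or K19R day 10 replicate 1 (0.063). Pax6 was not called without FLAG-WT day 0 replicate 2 (0.052), FLAG-WT day 10 replicate 2 (0.1), K19R day 0 replicate 1 (0.072) or K19R day 10 replicate 2 (0.05). With library totals only, Klf4 (-0.21, adjusted p = 0.14), Gata1 (adjusted p = 0.051) and Pax6 (adjusted p = 0.072) were not called, and Eed (0.36, adjusted p = 0.01), Ezh2 (0.36, adjusted p = 0.0019), Suz12 (0.33, adjusted p = 0.012), Jarid2 (0.35, adjusted p = 0.0032) and Gata4 (0.52, adjusted p = 0.021) passed as well, as the median of all genes went from 0.16 to 0.49. Gata4 also passed without FLAG-WT day 0 replicate 1 (0.45, adjusted p = 0.043).

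Endoderm transcripts stood high in FLAG-WT day 0 replicate 2, with Afp at 55 CPM against 1.78 in replicate 1. The EED genotype gives no difference between libraries of the same line, and whether it also lowers these transcripts in K19R stays open: without replicate 2 the list was not called (median -0.25, camera adjusted p = 0.67, 2 of 22 members lower and 3 higher), while Afp was still lower (-3.08, adjusted p = 0.0039) and Ttr (-2.33) and Apoa1 (-2.33) did not pass. RNA or reads of an embryoid body sample may have entered that library: 7 genes of at least 500 CPM in K19R day 10 and at most 1 CPM in K19R day 0 exceeded replicate 1 by a similar share of their day 10 level, 0.349% to 0.483% (10th to 90th percentile, ratio 1.39, the lowest of the 3 embryoid body groups with at least 5 such genes). Over 32 genes of at least 100 CPM the ratio was 2.44, and with FLAG-WT day 10 as the source it was 2.35 and 14.9. A few endoderm-type cells in that culture stay open as well and were not tested.

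Y-linked transcripts were lower in FLAG-WT at all 4 days. That K19R raises them was argued against, as the wildtype mESCs exceeded FLAG-WT by a median of 4.37 log2, as far as those cells, in another medium and of a relation to the lines not stated, stand for cells without the substitution. Loss of the Y chromosome in part of the FLAG-WT cells stays open: it needs 1 common share of the K19R level for Ddx3y, Eif2s3y and Uty, and these kept 16%, 13.2% and 13% at day 0 (ratio of highest to lowest 1.23), but 14.2%, 9.06% and 6.1% at day 10 (ratio 2.33, the largest of the 4 days). The ratio takes no account of the spread between libraries. Xist, whose strand is uncertain, stood lower in K19R at all 4 days. X-linked genes had a median of -0.136 in K19R over FLAG-WT at day 0, where medians of the autosomes ran from -0.054 to 0.062. At days 6 and 10 the X-linked median lay within the autosomal range. Whether these values share a cause with the Y-linked ones was not tested. K19R, taken here as the full level, itself stood below the wildtype mESCs. At day 0 FLAG-WT lacked 48.4, 28.7 and 13.1 CPM of the 3 genes against K19R, but 101, 87.1 and 38.8 CPM against the wildtype mESCs. Another explanation was that reads moved to the X-linked copies. Ddx3x, Eif2s3x and Kdm6a, chosen after the Y-linked values were seen, gained 112% of the CPM that the Y-linked genes lacked (101 of 90.3 CPM). This met the bound set in advance, but the sum cannot decide, as it rested on Ddx3x. Nor was it set against the X-linked genes as a whole, whose median was lower in K19R at day 0 too. Ddx3x gained more than Ddx3y lacked (178%), while Eif2s3x gained 40.2% and Kdm6a 25.3%. Against the wildtype mESCs the Y-linked genes lacked 227 CPM, while the X-linked copies changed by -52.6 CPM (-81.5, 20.2 and 8.74 by gene). For Eif2s3y and Uty these values argue against moved reads as the whole cause in both comparisons. For Ddx3y they do so only against the wildtype mESCs, which were grown in another medium.

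The formative and primed epiblast list was higher in K19R embryoid bodies at days 6 and 10 and the naive and general pluripotency lists at day 10, while at day 6 their calls were lost with an estimated correlation (adjusted p = 0.35 and 0.11) and Klf4 and Klf2 were lower. As to the scaling of the libraries, the formative and primed epiblast list had a median of at least 3.04 log2 at day 10 under TMM, RLE size factors and library totals. A change of scaling moves all genes together, and the median of all genes ran only from 0.07 to 0.44 over these 3. None of them could therefore have removed the difference, and the test shows only that the choice among the 3 does not account for it. A delay of all steps from day 0 on was not decided: at day 2 the endoderm list, which rose in FLAG-WT, was lower in K19R (median -2.77, adjusted p = 0.013 with an estimated correlation), while the naive pluripotency list, whose median in FLAG-WT fell further at each day, was lower in K19R as well (median -0.71), a call lost with an estimated correlation (adjusted p = 0.12). A share of cells left in the day 0 state may contribute and was not decided: 214 genes of at least 20 CPM in K19R at day 0, and at least 20 times their FLAG-WT day 10 level, were in K19R at day 10 at 2.54% to 23.6% of their day 0 level (10th to 90th percentile, ratio 9.33). For the epiblast list the median excess in K19R over FLAG-WT at day 10 was 81.1% of the K19R day 0 level. It was 104% for Dnmt3b and 218% for Cdh2, over a range of -46.2% for Pou3f1 to 27200% for Fgf5. The median lay above the 23.6% of the 214 genes. It was below the whole day 0 level, the bound set for arguing against such cells, so it did not decide. It rested in part on members nearly absent from K19R at day 0, such as Fgf5 (0.0233 CPM) and Fgf8 (0.125 CPM). The excess of Cdh2 and Fgf5 was above their whole day 0 level, which such cells alone cannot give. Nodal (13.8%) and Lefty2 (22.5%) lay within the range of the 214 genes, and Dnmt3a (-2.03%) and Pou3f1 below it. For the epiblast list as a set, and for the naive and general pluripotency lists, such cells stay open. The K19R substitution itself stays open for all these lists, as it was not tested apart from other differences between the lines.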

How the results depend on the processing

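The alternatives without X- and Y-linked genes and with crossed replicate numbers, and the split of simulated genes by level, were added after seeing the data, and the others were planned. Counts of called genes in the 14 comparisons moved by at most 1.5 times with RLE size factors, library totals, no filter, the stricter filter, gene classes removed, DESeq2, the replicate block and no X- and Y-linked genes. With a fold of at least 2 required as well, 329, 2215, 4690 and 4754 genes passed at days 0, 2, 6 and 10, 4866 in FLAG-WT at day 2, 4991, 7996 and 8545 in K19R at days 2, 6 and 10, 1680, 3883 and 4049 for the genotype change, and 6050 for the wildtype mESCs, by construction of that rule. In a fit of its own 4 libraries, day 0 had 4014 calls (2003 in the fit of 16), and the cause was not tested. Leaving out 1 library gave 844 to 957 calls at day 0, with fewer samples, 5859 to 6987 at day 2, 9705 to 9948 at day 6, 9444 to 10249 at day 10 and 10320 to 11493 for the wildtype mESCs. Library totals turned Suz12 at day 6 to 0.11 and Gata6 at day 10 to 0.10, as the median of all genes moved up with them. With the replicate block, 1921, 7868, 11092 and 11041 genes were called at days 0, 2, 6 and 10. The 28 pairs of same-numbered samples had correlations of -0.171 to 0.173, so the numbers were not taken to pair the samples. Crossing the numbers, run for 2 comparisons, gave 11109 calls at day 10 and 10736 in K19R at day 2. Without X- and Y-linked genes 1883, 7662, 10769 and 10762 genes were called. Of 392 list tests 152 were called, and 88 of these calls were lost with an estimated correlation. The block ended 2 list calls and made 3, and RLE size factors ended 1 and made 2. Leaving out 1 library ended a list call 24 times and made one 21 times. Of 297 tests of named genes 243 were called. Besides turning and ending those of Suz12 and Gata6, library totals ended 8 calls and made 16 others, DESeq2 ended 5 and made 1, no filter ended 3 and made 3, the stricter filter ended 4, fits of only the libraries compared ended 2 and made 2, RLE size factors ended 1 and made 1, and the block, its crossed form and the removals of gene classes or of X- and Y-linked genes changed none. Leaving out 1 library ended a gene call 56 times, made one 7 times and turned and ended 2 for FLAG-WT at day 2, Afp (-4.29 to 0.65) and Apoa2 (-3.25 to 0.74), both above 0 without the day 0 replicate 2. On simulated counts with day 0 means, 1.75% of genes changed 1.5-fold were recovered under 5 CPM and 91.2% at or above it, and with day 10 means 10% and 88.9%, so most 1.5-fold changes of genes under 5 CPM would be missed at this depth.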

Other observations

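The tests of the lists named here were fixed before the data were examined, and the chromosome medians were chosen only after the results were seen. Several tissue lists were called in neither direction between K19R and FLAG-WT at day 10. Of 21 cardiac and muscle members 9 were higher and 6 lower, and 9 and 7 adjusted over the list alone (camera adjusted p = 0.74), with the myosin gene Myh7 at -3.69 ± 0.17 SE and Acta2 at 5.06 ± 0.18. Of 14 trophoblast members 8 were higher and 3 lower (camera adjusted p = 0.11), of 13 endothelial members 8 and 3 (camera adjusted p = 0.075) and of 11 blood members 5 and 2 (camera adjusted p = 0.74), each also over the list alone. Of 18 germ cell members 8 were higher and 3 lower (camera adjusted p = 0.13) and of 29 imprinted genes 12 higher and 10 lower (camera adjusted p = 0.88), also over the list alone. The imprinted list had a median of -0.01, also with the member at 0 counts at its bound, a mean above 0 and a test in the lower direction, and its median was 0.30 with library totals only. Of 16 neural progenitor members 3 were higher and 5 lower, also over the list alone (camera adjusted p = 0.17), with a median of 0.46 (0.06 with members at 0 counts at their bound), a mean above 0 and a test in the lower direction, and Nes at -1.80 ± 0.08. Of 40 other Polycomb target regulators 11 were higher and 12 lower, also over the list alone (camera adjusted p = 0.34), with a median of -0.10, also with members at 0 counts at their bound, that was 0.21 with library totals only.

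The median of X-linked genes in K19R over FLAG-WT was -0.136 at day 0, -0.202 at day 2, -0.219 at day 6 and 0.078 at day 10 (349 genes with a log2 CPM above 3). Medians of the 19 autosomes ran from -0.054 to 0.062 at day 0, -0.123 to 0.033 at day 2, -0.265 to -0.077 at day 6 and -0.078 to 0.081 at day 10, so that at days 6 and 10 the X-linked median lay within their range. In wildtype mESCs over FLAG-WT, the medians of chromosomes 11 and 8 were -0.407 and -0.26, and those of the other autosomes ran from -0.047 to 0.189.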
